A study of Homo sapiens with 6 samples.

How the data were processed

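Poly(A)-selected RNA from the human squamous carcinoma cell line SAS was sequenced in 6 libraries, 3 from cells given a control siRNA and 3 from cells given an siRNA against IGF2BP1. Per the labels' protocols, total RNA was extracted with TRIZOL, mRNA was captured on oligo-dT beads, and strand-marked (dUTP) libraries were made from randomly primed cDNA. The labels give replicate numbers and do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The labels do not give the siRNA sequence or say whether it is a single sequence or a mixture.

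The deposited table holds raw read counts per gene, 1 column per library, for 62700 genes. Per the submitters' processing notes, which list tools without order or settings, cutadapt 2.8, HISAT2 2.1.0, SAMtools 1.10, featureCounts 2.0.0 and the genome build hg38 were used. The annotation release, the strand setting of the counting and the treatment of reads that map to several genes are not given in the sources used here. Values of genes that share sequence with near-identical copies, or exons with a neighbour on the opposite strand, are therefore uncertain, and overlaps of exons with an opposite-strand gene are given in the report. The deposited table also gives a gene length in bases, another column as the authors made it, which was used only to check length trends. All 37 genes of the mitochondrial chromosome hold 0 reads in all 6 libraries, so the list of mitochondrially encoded genes gave no result. Gene symbols in the table have hyphens replaced by dots; 5521 symbols were restored by Ensembl identifier, and 20357 genes without a symbol are kept under their identifier. Each column was matched to its sample by the library name in the labels, and 0 columns of per-sample values were left unused.

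Library totals were 23775889, 23833658 and 26675064 reads for controls 1 to 3 and 17918496, 21424075 and 25926371 reads for knockdowns 1 to 3. At these depths 3 reads correspond to between 0.115 and 0.165 CPM, the count scaled to library size; such floors and counting intervals cover counting error only. Replicates of a group differed by far more than sampling noise: the chi-square of their counts per degree of freedom, over genes with at least 20 reads in the pair, lay between 14.8 and 36.9, so no library was counted as a copy of another.

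Genes were kept with filterByExpr (default minimum count of 10 and minimum total of 15), which left 14649 genes. They were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling factors, robust dispersion estimation, glmQLFit and glmQLFTest, 2 groups and no covariate, with Benjamini-Hochberg adjustment over the tested genes. A gene was called at an adjusted p under 0.05. CPM values are TMM scaled. The standard error (SE) of a log2 fold change is the fitted coefficient divided by the square root of its quasi-F statistic, and 95% intervals use the degrees of freedom of that test. Fold changes are knockdown over control.

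Before the data were examined, 30 gene lists were fixed. A list with at least 3 tested members was tested two-sided with camera in limma 3.58.1 on log2 CPM (prior count 2, preset inter-gene correlation 0.01) and adjusted over the 26 lists tested. This test compares the members of a list with the other tested genes, so its direction is relative to those genes. The median log2 fold change of all tested genes was 0.033. The list of the IGF2BP family was left out of these tests, since it holds the targeted gene, and the leukocyte and melanocyte lists had too few tested members. Members are also counted with p-values adjusted over the list alone. The genes named were set by a rule: a fixed group around IGF2BP1 and YAP1, the 10 largest rises and 10 largest falls among called protein-coding genes with at least 5 CPM in the higher group and no overlap between groups, and up to 2 called members per direction from each list. Coordinates come from GENCODE release 29 on GRCh38, the assembly called hg38, and were found for 91 of the 92 genes named by the rule. Some genes that the rule names are not reported here.

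The alternatives fixed in advance were RLE scaling, no scaling factor, no count filter, a stricter filter (5 CPM in 3 libraries), the replicate number as a block, leaving out each library, DESeq2 1.42.0, limma-voom, a minimum fold of 1.2 (glmTreat), camera with an estimated correlation, and fry. Whether replicate numbers pair the libraries was checked from the correlation of deviations from the group means.

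The fit was tested on simulated data: in 10 simulations of this comparison over 14649 genes, with 200 genes changed in each, 12.5% of genes changed 1.5-fold, 50.4% of those changed 2-fold and 81.8% of those changed 4-fold were called in the right direction. Of all 1100 simulated calls, 82 (7.45%) were unchanged genes, more than the nominal 5%. The real comparison called 1893 genes, many more than the 200 changed in a simulation. The p cut-off set by the adjustment therefore differs, and the shares recovered do not carry over to the real comparison. In a simulated list test over 28 lists of 20 genes, the list raised 1.5-fold was called and 0 of the others were. Genes were drawn independently of each other there, so this does not show how often lists of correlated genes are called wrongly. A search for 7-base words in 3' UTRs, scored by the mean residual log2 fold change on 3' UTR length and GC content with 1000 permutations of genes, recovered 3 of 3 planted words, each with a planted fall of 0.4.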

Results

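The series measured mRNA by RNA sequencing in SAS cells, a line derived from a squamous cell carcinoma of the tongue, after knockdown of IGF2BP1, an RNA-binding protein that stabilises many of the transcripts it binds. Its single comparison sets 3 IGF2BP1 siRNA libraries against 3 control siRNA libraries, and the stated question is whether IGF2BP1 counteracts the shut-off of YAP1, the transcriptional coactivator held in check by the Hippo kinases. Depth ranged from 17918496 counted reads (knockdown 1) to 26675064 (control 3), and between 19392 and 20392 genes had at least 1 read. Knockdown 1 was the shallowest library and had the most genes detected. The first principal component of log2 CPM held 38.6% of the variance and separated the groups.

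IGF2BP1 (ENSG00000159217; GRCh38 chromosome 17, 48997412 to 49055650, plus strand) was lower in each knockdown library than in each control library. Control libraries held 185, 223 and 292 reads and knockdown libraries 29, 25 and 21, which gave 9.64 ± 1.55 CPM in controls and 1.16 ± 0.399 CPM after knockdown (SD, n = 3 each). The log2 fold change was -3.07 (SE 0.30, adjusted p = 4.56e-06). The paralogs were not called: IGF2BP2 had a log2 fold change of 0.27 (adjusted p = 0.554) and IGF2BP3 of -0.48 (adjusted p = 0.374). A gene on the opposite strand shares 17.9% of the exon bases of IGF2BP3, so that value is uncertain.

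YAP1 (ENSG00000137693; chromosome 11, 102110461 to 102233423, plus strand) was not called at 11.6 ± 2.60 CPM in controls and 9.56 ± 2.32 CPM after knockdown (SD, n = 3 each). Its log2 fold change was -0.29 (SE 0.23, adjusted p = 0.486), with a 95% interval from -0.77 to 0.20. The YAP1 paralog gene WWTR1, which encodes TAZ, had a log2 fold change of 0.01, and the DNA-binding partners TEAD1 and TEAD4 had 0.72 and -0.15, none of them called. The widely used YAP reporters CCN1, CCN2 and ANKRD1 had log2 fold changes of 0.00 (95% interval -0.22 to 0.22), 0.19 (-0.32 to 0.69) and 0.59 (0.07 to 1.11); their adjusted p-values were 0.998, 0.681 and 0.133. CCN1 was among the more abundant transcripts, at 1667 ± 113 CPM in controls and 1668 ± 162 CPM after knockdown (SD, n = 3 each). WWTR1 and CCN1 changed sign with RLE scaling (-0.0027 and -0.015). An antisense gene shares 9.97% of the exon bases of YAP1, 9.45% of those of WWTR1 and 8.34% of those of CCN2.

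Of 20 tested core YAP/TAZ target genes, 2 rose and 2 fell. The receptor tyrosine kinase gene AXL rose (log2 fold change 0.67, adjusted p = 0.0109), as did NT5E, which encodes a surface ectonucleotidase (0.57, adjusted p = 0.0361), while AMOTL2, a Hippo scaffold, fell (-0.41, adjusted p = 0.0195) with IGFBP3 (-0.37, adjusted p = 0.0363). Without knockdown 1, the rise of AXL was 0.43 (adjusted p = 0.0108). Adjusted over the list alone, 2 were higher and 3 lower. The list as a whole was not called (median log2 fold change 0.05, adjusted p = 0.768). A wider conserved YAP signature had 9 of 53 tested members higher and 4 lower (10 and 6 adjusted over the list alone; adjusted p = 0.497), with VIM (1.38) among the rises and SGK1 (-0.84) among the falls. In the list of Hippo pathway components, MOB1B and FRMD6 rose, AMOTL2 fell and 24 of 27 were not called (2 higher and 1 lower adjusted over the list alone; adjusted p = 0.497). MOB1B rests on 3 reads in the controls and 31 after knockdown, a ratio of 11.1 with a 95% counting interval from 3.46 to 56.8.

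**Figure D1:**
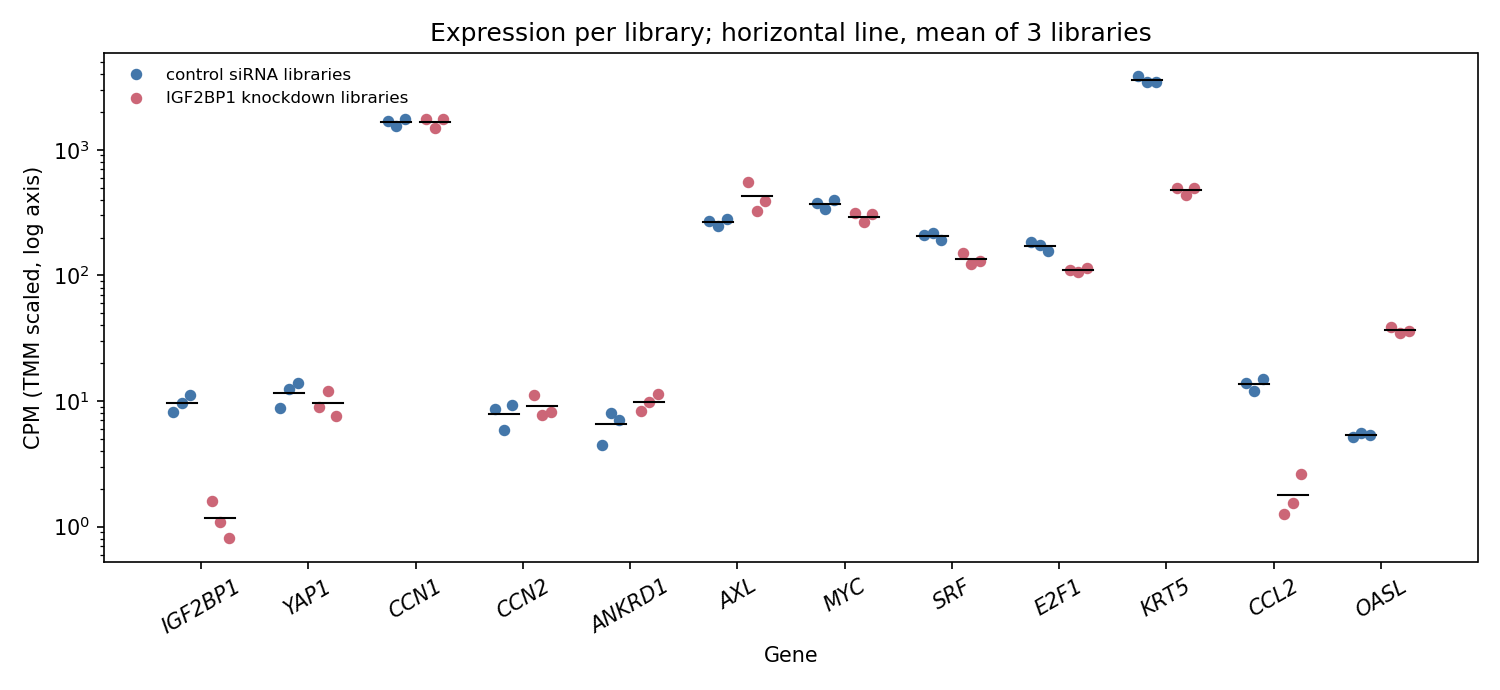
Expression of 12 genes in each library, in TMM-scaled CPM on a log axis, with control siRNA libraries in blue, IGF2BP1 knockdown libraries in red and a line at the mean of 3 libraries. IGF2BP1, KRT5 and CCL2 are lower in each knockdown library, OASL is higher, and the groups overlap for YAP1, CCN1 and CCN2. ANKRD1, which was not called, is higher in each knockdown library than in each control library.

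Among transcripts reported as IGF2BP1 targets, E2F1, E2F2, SRF and MYC fell while PDLIM7 and ITGB5 rose. E2F1, which drives entry into S phase, fell from 172 ± 13.2 to 110 ± 3.66 CPM (SD, n = 3 each; log2 fold change -0.64, adjusted p = 5.39e-04), and SRF, the serum response transcription factor, from 206 ± 14.2 to 135 ± 13.9 CPM (-0.61, adjusted p = 0.00109). E2F2 had a log2 fold change of -0.79 (adjusted p = 0.016). The fall of MYC was small (-0.34, adjusted p = 0.0449) and its call was lost without control 1, control 3, knockdown 2 or knockdown 3, with adjusted p-values of up to 0.131. HMGA2 was not called (-0.04, adjusted p = 0.908; the sign turned with no scaling factor), and LIN28B had 0 reads in all 6 libraries. Of the 22 tested members of this list, 2 were higher, 4 lower and 16 not called, with the same counts adjusted over the list alone. The list test gave an adjusted p of 0.664; its direction was lower while the median (0.04) and mean (0.02) of its members were above 0. In the list of m6A writers, erasers and readers, METTL3, the catalytic subunit of the methyltransferase, was the called member (-0.55, adjusted p = 0.0104), the other 14 were not called, and adjusted over the list alone 0 were higher and 1 lower (list adjusted p = 0.262).

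Across all 14649 tested genes, 918 were higher and 975 lower after knockdown, and 352 of the former and 214 of the latter changed by at least 1 on the log2 scale. Among called protein-coding genes with at least 5 CPM in the higher group and no overlap between groups, the largest falls were in CCDC6 (-3.09), IGF2BP1, the basal keratin KRT5 (-2.91), the chemokine CCL2 (-2.89), HDLBP (-2.74), the protease KLK13 (-2.60), the simple-epithelial keratin KRT7 (-2.53), the chemokine CXCL2 (-2.37), BZW2 (-2.23) and ABCB8 (-2.19). KRT7 (chromosome 12, 52232520 to 52252186) fell from 9425 ± 269 to 1628 ± 86.4 CPM and KRT5 (chromosome 12, 52514575 to 52520687) from 3584 ± 233 to 477 ± 32.9 CPM (SD, n = 3 each). HDLBP (chromosome 2, 241227264 to 241317061), which encodes the RNA-binding protein vigilin, fell from 253 ± 28.8 to 38.0 ± 2.71 CPM. By the same rule, the largest rises included those of CRCT1, a gene of the epidermal differentiation complex (3.23), and the interferon-induced OASL (2.77). Also included were the neurotensin receptor NTSR1 (2.49), the kisspeptin gene KISS1 (2.46), the matrix metalloproteinase MMP3 (2.31) and LAPTM5 (2.22). The G protein-coupled receptor kinase GRK5 (2.15), CCK (2.00) and CPA5 (1.99) were included too. An antisense gene shares 33.2% of the exon bases of CCK, which makes its value uncertain. The share of higher among all calls was 48.5%, and 63.2% with no scaling factor, which moved the median of all genes by 0.08. The median log2 fold change was 0.20 in the lowest quintile of expression level and -0.05 in the highest. Groups did not overlap for 4493 of the tested genes (30.7%; chance gives 10%). The number of higher genes was 585 without control 1, 529 without control 2 and 587 without knockdown 3, and the total of 1893 was 1231 without control 2 and 1948 without knockdown 1.

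**Figure D2:**
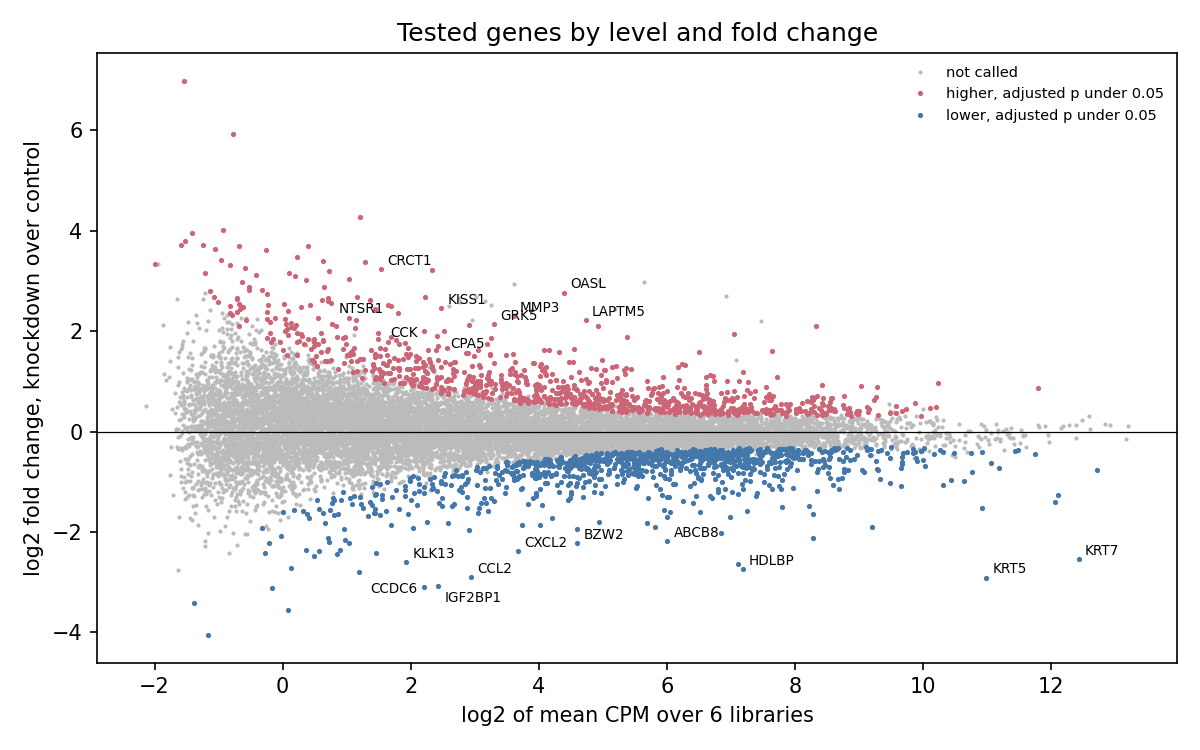
The log2 fold change of each tested gene against the log2 of its mean CPM over 6 libraries; red points are the 918 genes called higher and blue points the 975 called lower at an adjusted p under 0.05. KRT7 and KRT5 stand out as large falls at high expression and OASL as a large rise.

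Inflammatory genes driven by NF-kB fell together. Of 19 tested members 13 fell and 1 rose (14 and 1 adjusted over the list alone). The chemokine genes CXCL2 (-2.37), CCL20 (-1.49), CXCL8 (-1.43) and CXCL1 (-1.28) fell with IL6 (-1.24), and CSF2 rose (0.43, adjusted p = 0.0348). The list test gave an adjusted p of 4.55e-08 with the preset correlation, and an adjusted p of 0.156 with an estimated correlation.

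Genes of the G1/S transition and DNA replication were lower: 16 of 34 fell and 0 rose (19 and 0 adjusted over the list alone). CCNE1, which encodes cyclin E1, fell from 21.8 ± 2.55 to 9.18 ± 1.91 CPM (SD, n = 3 each), and CDC25A, a phosphatase that activates cyclin-dependent kinases, had a log2 fold change of -1.02 (SE 0.13). The list had an adjusted p of 1.38e-06, and an adjusted p of 0.128 with an estimated correlation. That estimate was 0.0057, below the preset 0.01, so a higher correlation did not end the call. Mitotic genes were not called as a list (adjusted p = 0.423), with 1 of 27 members lower, CDC25C, and 0 lower adjusted over the list alone. Of the MYC-responsive ribosome biogenesis genes, NOP56 and RRS1 fell among 26 (2 lower adjusted over the list alone; list adjusted p = 0.0634). Among 49 cytosolic ribosomal protein genes 3 fell, RPL10, RPLP1 and RPLP2 (1 lower adjusted over the list alone; list adjusted p = 0.085); a gene on the opposite strand shares 34.2% of the exon bases of RPL10, and ribosomal protein genes have many processed copies, so these values are uncertain. Without 1 library both lists could pass the threshold: the MYC-responsive list without control 1, control 3 or knockdown 2 (adjusted p from 0.0067 to 0.0429), and the ribosomal list without control 1, knockdown 2 or knockdown 3 (from 0.00329 to 0.0204).

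Sterol synthesis genes were lower. Of 23 tested genes of cholesterol synthesis and uptake 7 fell and 0 rose (12 and 0 adjusted over the list alone), among them DHCR7, an enzyme of the final steps, from 846 ± 15.1 to 438 ± 43.6 CPM, and INSIG1 (-0.88), a brake on sterol synthesis. The list had an adjusted p of 5.45e-06, and an adjusted p of 0.156 with an estimated correlation. Of 22 hypoxia and glycolysis genes 5 rose and 1 fell (8 and 1 adjusted over the list alone); CA9, a carbonic anhydrase induced by low oxygen, rose by 1.73 and BNIP3 by 1.33 on the log2 scale, and PGAM1 fell. That list had an adjusted p of 0.00998, and an adjusted p of 0.344 with an estimated correlation. A gene on the opposite strand shares 38.5% of the exon bases of CA9, so its value is uncertain.

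Keratinocyte genes moved in both directions. Of 18 basal squamous genes 7 fell and 2 rose (8 and 2 adjusted over the list alone). KRT5 and KRT6A (-2.02) fell, as did the laminin gene LAMB3 (-0.98), while KRT15 (0.99) and KRT16 (0.92) rose. The list was lower with an adjusted p of 0.00406, and an adjusted p of 0.156 with an estimated correlation. KRT6A and KRT16 have near-identical copies and their values are uncertain. Among 15 tested genes of squamous differentiation LCE3D, IVL, KLF4 and KRT10 rose and S100A7 and GRHL3 fell (4 and 2 adjusted over the list alone; list adjusted p = 0.39, and 0.00713 by fry). IVL, which encodes the envelope protein involucrin, rose from 0.851 ± 0.111 to 4.57 ± 1.14 CPM (SD, n = 3 each). LCE3D rested on 3, 1 and 2 reads in controls 1 to 3 and 16, 33 and 13 in knockdowns 1 to 3.

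In the epithelial junction list, the E-cadherin gene CDH1 fell from 138 ± 17.3 to 45.4 ± 6.25 CPM and the epithelial transcription factor ELF3 from 194 ± 2.40 to 59.7 ± 4.63 CPM (SD, n = 3 each), while CLDN4 and CLDN3 rose. CLDN4 went from 331 to 538 CPM. CLDN3 rested on 8, 8 and 10 reads in controls 1 to 3 and 27, 38 and 22 in knockdowns 1 to 3. Antisense genes share 5.62% of the exon bases of CDH1 and 9.23% of those of ELF3. Of its 26 members 2 were higher and 4 lower (4 and 5 adjusted over the list alone; list adjusted p = 0.497). Of 19 mesenchymal genes 3 rose and 2 fell (4 and 5 adjusted over the list alone): VIM (1.38), the gene of the intermediate filament vimentin, rose (12.4% of its exon bases are shared with an antisense gene), and MMP14 (-0.64) and TGFBI (-0.41) fell. The list had an adjusted p of 0.664 in the lower direction, with a median of -0.13 and a mean of 0.06. Among 25 integrin and focal adhesion genes 5 fell and 1 rose (6 and 3 adjusted over the list alone; list adjusted p = 0.16), including the laminin genes LAMA5 (-1.06) and LAMB3 and, as the rise, ITGB5. Targets of SRF and its MRTF coactivators split into falls of EGR1 (-2.11) and FOS (-1.44) and rises of MYL9 (0.88) and CNN2 (0.69), with 3 higher and 5 lower of 24 (7 and 5 adjusted over the list alone; list adjusted p = 0.768 in the higher direction, median 0.18, mean -0.05). Of 22 immediate early and stress genes 8 fell, with EGR1 and EGR3 (-1.65) the largest, and 2 rose, ETV5 (1.03) and ETV4 (0.49) (8 and 3 adjusted over the list alone; list adjusted p = 0.108, but 0.0316 without control 2 and 0.0483 without knockdown 1).

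Interferon-stimulated genes were higher: 6 of 20 tested members rose and 0 fell, with the same counts adjusted over the list alone. IFIT1 (3.01), OASL (2.77), ISG15 (1.95), IFI44 (1.79), IFIT3 (1.37) and ISG20 (0.56) rose, and OASL (chromosome 12, 121019111 to 121039242) went from 5.38 ± 0.214 to 36.7 ± 1.92 CPM (SD, n = 3 each). The list had an adjusted p of 0.00645, and an adjusted p of 0.156 with an estimated correlation. With the stricter count filter, which removes low members such as IFIT1, the adjusted p was 0.145.

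Replication-dependent histone genes, whose transcripts mostly lack poly(A) tails, were higher as a list, with 4 of 22 risen and 0 fallen (6 and 0 adjusted over the list alone) and a median log2 fold change of 0.63. H3C2 (3.16), H4C3 (1.82), H2AC6 (1.33) and H4C14 (1.32) rose from low levels, and they have near-identical copies, so single members are uncertain. The list had an adjusted p of 1.22e-04, and an adjusted p of 0.156 with an estimated correlation; with the stricter filter it had too few members for a test. Other RNAs without poly(A) tails differed between libraries: RNA5-8SN3, a ribosomal RNA gene, stood at 543 CPM in knockdown 1 and between 21.3 and 50.7 CPM in the other libraries, and RN7SL1, the signal recognition particle RNA, at 368, 447 and 60.1 CPM in knockdowns 1 to 3 against 33.9, 139 and 18.3 CPM in controls 1 to 3.

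Of 12 heat shock genes 3 fell and 0 rose (5 and 0 adjusted over the list alone), with HSPA8 (-0.57) and HSPB1 (-0.43) as the largest. The list had an adjusted p of 0.0166, an adjusted p of 0.156 with an estimated correlation, 0.0696 with the stricter filter and 0.073 by fry. The unfolded protein and integrated stress response list had 4 of 20 members lower, with PDIA4 (-0.74) and XBP1 (-0.57) the largest falls (4 lower and 1 higher adjusted over the list alone; list adjusted p = 0.0634). That list passed without control 1, control 2 or knockdown 3 (adjusted p from 0.0471 to 0.0486) and by fry (0.00713). Among 19 p53 targets GDF15 (-0.64) and FDXR (-0.50) fell and 0 rose (2 lower adjusted over the list alone; list adjusted p = 0.498, in the lower direction while the median was 0.06).

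Markers of other cell types were read as a check on what else the cultures could hold. Of 12 fibroblast markers 4 were tested, of which PDGFRB rose from 0.605 to 1.73 CPM (adjusted p = 0.0491; 1 higher adjusted over the list alone; list adjusted p = 0.73). Of 10 endothelial markers 4 were tested and 0 called, also adjusted over the list alone (list adjusted p = 0.423). Leukocyte and melanocyte markers had 2 tested members each, of which 0 were called over all genes; adjusted over the list alone, 1 leukocyte marker was lower. The most abundant leukocyte marker was CD14 at 17.8 CPM in controls and 13.1 CPM after knockdown, and PTPRC was at 0 in all libraries.

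**Figure D3:**
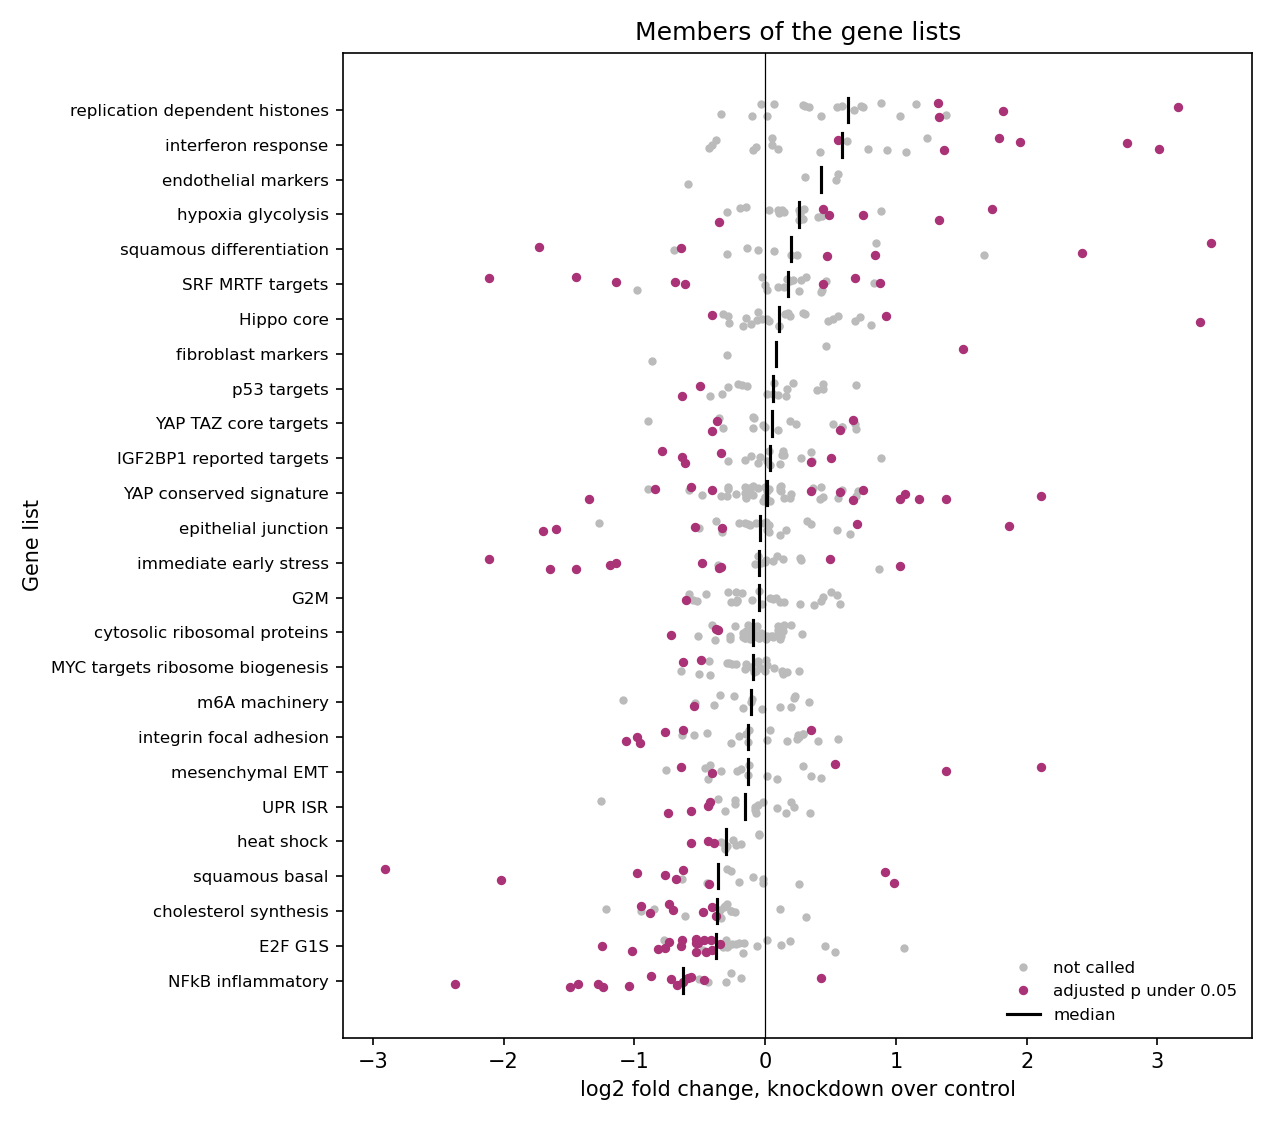
The log2 fold change of each tested member of the 26 gene lists tested; purple points are called at an adjusted p under 0.05 and a vertical bar marks the list median. The medians of the NF-kB, G1/S and cholesterol lists lie below 0 and those of the histone and interferon lists above it; the median of the core YAP/TAZ targets is 0.05.

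Calls near the threshold depended on single libraries. Of the 81 called genes named by rule besides IGF2BP1, 60 kept their call and direction in each alternative that tested them, apart from the minimum fold of 1.2, which was read only as a count. The other 21 lost the call in at least 1 of the fits without a library, where fewer samples remain, and kept their direction. CDC25C and PDGFRB were called in 0 of the 6 such fits, with adjusted p-values of up to 0.129 and 0.186, and MOB1B in 0 of the 5 that tested it (up to 0.163). CSF2 (up to 0.163) and NT5E (0.158) kept it only without knockdown 1, and CLDN3 (0.150) only without knockdown 3. ITGB5 (0.251) and MYL9 (0.121) kept it only without knockdown 2. H3C2 lost it without control 1, control 2, knockdown 1 or knockdown 3 (up to 0.0758). H4C3 lost it without control 2, control 3, knockdown 2 or knockdown 3 (up to 0.143) and stood at 2.75 without control 1. RPLP1 lost it without knockdown 1 or any 1 control (up to 0.110). GRHL3 (0.115) and HSPA8 (0.0754) lost it without control 2, control 3 or knockdown 1, and HSPB1 (0.103) and IGFBP3 (0.103) without control 1, control 3 or knockdown 2. RRS1 lost it without control 1, control 2 or knockdown 3 (up to 0.0993), AMOTL2 without control 1 or knockdown 3 (0.0875), LCE3D without control 2 or knockdown 2 (0.0875) and PGAM1 without control 1 or control 2 (0.0539). Other alternatives also ended calls. With no scaling factor MYC, IGFBP3, CDC25C and RPLP1 lost the call (adjusted p from 0.0612 to 0.103), with RLE scaling ITGB5 (0.0585), with no filter MOB1B (0.130) and PDGFRB (0.0564), and with the strict filter RPLP1 (0.0665). The replicate block ended those of CLDN3 (0.0527) and MOB1B (0.0740), limma-voom those of CLDN3 (0.0698), ITGB5 (0.0543) and PDGFRB (0.0605), and DESeq2 that of PDGFRB (0.0539).

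Reads from an overlapping gene could also enter other values given above. A gene on the opposite strand shares 9.27% of the exon bases of CNN2, 8.78% of those of CDC25C, 6.89% for KRT7, 6.58% for METTL3, 3.80% for BZW2, 3.38% for EGR3, 2.49% for HMGA2 and 2.22% for ABCB8. The share was 1.90% for HDLBP, 1.89% for ETV4, 1.71% for LAMA5, 1.56% for MMP3, 1.30% for AXL and 0.834% for IGF2BP1. A gene on the same strand shares 11.4% of the exon bases of RRS1.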

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

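The fall of IGF2BP1 and the absence of a call for YAP1 held under each alternative run, apart from the minimum fold of 1.2, which was read only as a count. Of the 1893 called genes, 1849 were shared with RLE scaling, 1686 with no scaling factor, 1854 with no filter, 1588 with the strict filter, 1875 with DESeq2 and 1774 with limma-voom, and 0 shared calls changed sign. The replicate block gave 2431 genes, 1874 of them shared; same-number libraries correlated at 0.18, 0.09 and -0.07 in their deviations from the group means, so the numbers were not read as pairs. Genes changed by at least 1 on the log2 scale numbered 298 with the strict filter, which tests fewer genes. A minimum fold of 1.2 left 972 genes, 490 higher and 482 lower. Leaving out 1 library gave 1231 to 1948 genes, of which 529 to 828 were higher.

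Called lists numbered 13 with no filter, 5 with the strict filter and 0 with camera and an estimated correlation. The estimate was 0.0057 for the G1/S list, -0.0031 for the interferon list and -0.00091 for the heat shock list. These lie below the preset 0.01, so a higher correlation did not end those calls. For the other called lists the estimate ran from 0.0166 (basal squamous) to 0.102 (cholesterol). The replicate block called 9, adding the MYC-responsive list (adjusted p = 0.0455). By fry 9 were called, 7 of them shared, with squamous differentiation and the unfolded protein response added (0.00713 each). No filter added integrin, unfolded protein response, MYC-responsive, ribosomal and immediate early lists (0.0266 to 0.0484), and leaving out 1 library gave 9 to 11 lists. The strict filter left the histone list too few members for a test. All 8 lists were called in each of the 6 fits without a library. The core YAP/TAZ list kept its side of the threshold without any 1 library (adjusted p from 0.590 to 0.948) and turned lower without control 2 (0.903). Directions of these uncalled results also turned, and the cause was not tested. WWTR1 had -0.0027 with RLE scaling, -0.0041 with no filter and -0.0065 with DESeq2, and -0.13 to 0.14 without 1 library. CCN1 had -0.015 with RLE scaling, -0.015 with no filter, -0.0019 with the replicate block, -0.019 with DESeq2 and -0.0028 with limma-voom, and -0.069 to 0.050 without 1 library. HMGA2 had 0.055 with no scaling factor and 0.0055 with the strict filter, and -0.25 to 0.061 without 1 library. Ranges without 1 library were -0.028 to 0.50 for IGF2BP2 and -0.0059 to 0.30 for CCN2. By fry the SRF/MRTF and mesenchymal lists turned (0.576 each). Without 1 library, list adjusted p-values ranged from 0.438 to 0.992 for SRF/MRTF targets, 0.430 to 0.940 for reported IGF2BP1 targets, 0.00329 to 0.799 for cytosolic ribosomal proteins and 0.523 to 0.948 for fibroblast markers.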

Other observations

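The tests of the S phase share, of the interferon list and of other splits for the lists, the look at 7SL, RMRP and rRNA genes, and the splits for the let-7 site were chosen after the results were seen. The genes in this paragraph and the next were also chosen after their values were seen, and no list of them was tested. KRT18 fell from 6222 ± 359 to 2600 ± 283 CPM (SD, n = 3 each; log2 fold change -1.26, adjusted p = 1.08e-06), and KRT8 (-0.77, adjusted p = 4.90e-05) and KRT19 (-0.59, adjusted p = 5.87e-04) fell as well. KRT7-AS, on the opposite strand of KRT7, fell (-2.64, adjusted p = 4.32e-09), and it shares 6.89% of the exon bases of KRT7. KRT81 (1.60, adjusted p = 6.64e-08), KRT86 (1.23, adjusted p = 8.47e-04), KRTAP2-3 (1.89, adjusted p = 9.04e-07) and KRTAP2-4 (1.67, adjusted p = 0.00146) rose; these have near-identical copies, so the values are uncertain. KRT17 was not called (-0.01, adjusted p = 0.952).

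SLC7A5 and SLC3A2, which encode the subunits of a large neutral amino acid transporter, fell, with log2 fold changes of -1.40 and -1.53. The complement gene C3 (-1.65), LCN2 (-1.94) and TNFAIP2 (-1.90) were lower as well.

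The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 1893 genes and the highest other 1, so 1 of 10 splits gave as many. For lists the real split called 8 and the highest other also 8, in the split of control 1, knockdown 1 and knockdown 2 against the rest, so 2 of 10 gave as many. The other splits called from 0 to 8 lists each, while calling at most 1 gene. In each other split, each side held 2 libraries given one siRNA and 1 given the other, so part of the siRNA difference remained. At the preset correlation, list calls there may come from that part or from differences between libraries. The number of lists called in a split thus does not decide whether the list calls given above come from the siRNA.

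Histone transcripts, with a list median of 0.63 (95% bootstrap interval 0.31 to 1.02), may have risen through the library or the cell. The G1/S list had a median of -0.37 (-0.52 to -0.26), but it had been called lower before this test was chosen. Transcript levels also do not count cells, so a larger share of cells in S phase stays open. For 2261 other protein-coding genes within the histones' range of lengths, 389 to 2881 bases, the median was 0.033 (0.013 to 0.056). That argues against a bias shared by genes over that whole range. These genes were not matched to the histones for level or within the range. Over all tested genes the median was 0.088 in the shortest quintile of length and 0.20 in the lowest quintile of level. Carry-over of RNA without poly(A) tails cannot be told apart from a change in the cells: the median of 34 small RNA genes was -0.23 (-0.38 to 0.26), under the bound of 0.316 set beforehand, but their mean was 0.19 and 15 of them were above 0, so that bound on the median does not decide. For 10 genes of 7SL, RMRP and rRNA, 5 of them among the 34 and 0 of them called, the median was 2.55, and 0.71 without knockdown 1. In knockdowns 1 to 3 the mean log2 CPM was 1.2, 1.37 and 0.82 for the 34 genes, 5.43, 3.99 and 2.36 for the 10 and 1.04, 1.17 and 1.07 for the histones, and in controls 1 to 3 it was 0.83, 1.17 and 0.55, then 1.89, 2.78 and 1.34, then 0.46, 0.32 and 0.10.

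For the interferon-stimulated genes, neither autocrine interferon signalling nor sensing of the siRNA itself can be told apart from other effects of the loss of IGF2BP1. Beside IFIT1, IFIT2, IFIT3, ISG15 and OASL, 5 genes set apart after their values were seen, the 15 other tested members of the list had a median of 0.10 (-0.09 to 0.63). They went both ways, so this median excludes nothing: IFI44 (1.79) and ISG20 (0.56) rose, and the uncalled ones ran from -0.43 (IRF9) to 1.24 (CMPK2). Sensing of the siRNA stays open because the design has 1 knockdown arm.

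Falls were searched for 7-base words in the 3' UTRs of 11617 coding genes, as an siRNA seed or unshielded microRNA sites might leave. Over 16352 words, 0 passed a family-wise permutation p of 0.05 in either direction (lowest for a fall 0.131). That met the bound set beforehand against a seed match, but the seed match stays open because a missed p excludes nothing and a mixture of siRNAs would dilute each seed. Among 30 listed microRNA sites, let-7 had the lowest adjusted permutation p, 0.0132, with a mean residual difference of -0.05 in 1271 genes. The let-7 difference cannot be told apart from differences between libraries, since the permutation treats genes as independent. Of 10 splits 2 scored as high (-3.33 for the real one and -3.37 for the other). That other split set control 1, control 2 and knockdown 3 against the rest. Part of the siRNA difference remained in it, so its score does not decide the question either.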
